A study of Homo sapiens with 6 samples.

How the data were processed

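Total RNA of Du145 prostate carcinoma cells, hybridised to 6 arrays, was extracted with Trizol, and 100 ng was labelled with biotin by a whole-transcript terminal labelling protocol, per the labels' protocols. Cells were grown in high-glucose medium with 10% serum and 5% CO2 at 37 °C, under 1% oxygen for 24 h. The deposited table holds 1 intensity per probe set and array on a linear scale, normalized with RMA per the submitters' processing notes, and the version of RMA, the probe definition and the genome build are not given in the sources used here. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of a set, so the arrays had been made alike in scale before deposit, and a change shared by most genes would be partly removed by it. The log2 of every deposited intensity lay within 6.99e-10 of a number with 2 decimals, so log2 values were used. Arrays have no read depth. Median intensities were 58.1 to 63.1, and intensities near the floor of 5.10 to 5.90 say little about change.

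Probe sets were named from the platform's annotation table. Of 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 are unnamed here. Gene identifiers of 19429 matched the GRCh38.p14 gene table, and 0 symbols needed an update. That table was used for names and gene spans only, and no coordinates are given. For each gene the probe set with the highest mean over all arrays was kept, which left 18417 genes, 769 of them with more than 1 probe set. Of 153 named genes 10 had another probe set, and 0 of those sets had a change of opposite sign. The other sets of TAP1, PSMB9, VARS1 and HLA-DMA gave the same change as the kept set, so they are no separate check. The kept set of VARS1 also had an adjusted p of 0.0893 with every probe set tested by limma. With every probe set tested by limma, the other sets of ATF4 (-0.24, adjusted p = 0.399, shTSC2 versus control), SAA2 (1.25, 0.0789, and -0.95, 0.200, shTSC2-adapted versus shTSC2), VARS1 (0.56, 0.0893, shTSC2 versus control) and NDUFV2 (0.51, 0.0514, shTSC2-adapted versus shTSC2) did not pass.

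Groups came from the labels: control, shTSC2 and shTSC2-adapted, with 2 arrays each. The tests, the gene lists, the rule for named genes and the alternatives, except those said to be added later, were fixed before the data were examined. One linear model per gene was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), so that the groups share one estimate of the spread with 3 residual degrees of freedom. P-values are two-sided and adjusted by Benjamini-Hochberg over 18417 genes, with a threshold of 0.05. The 34 gene lists, each with at least 5 genes tested, were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation per list and fry were run beside it. Counts of list members are given over all genes and adjusted over the list alone. Changes of TSC2 are also given as a percent of the control level with a 95% interval from the model.

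Named genes were TSC2, TSC1, RHEB, MTOR and DDIT4, and for each comparison the 10 largest rises and 10 largest falls among genes that passed and whose arrays did not overlap between the groups (filled up by the lowest unadjusted p where fewer passed, which was not needed), leaving out uncharacterised genes, small RNA genes and olfactory receptors. Added to these were the 2 largest rises and 2 largest falls of each list called by camera, and of the hypoxia, glycolysis, sterol, ATF4 and mTOR lists in any case. Other genes are named as chosen after their values were seen. The retained share is the covariance across genes of an shTSC2-adapted minus control difference with the shTSC2 minus control difference of the other arrays, divided by the covariance of the shTSC2 minus control differences of both array numbers. After the data were seen, all 8 combinations of arrays with no array on both sides were added. They were divided by the mean of that covariance over both pairings of shTSC2 with control arrays. Shared controls were simulated by 100 draws of unchanged groups.

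The gene model was tested on simulated data with 200 changed genes among 18417 in 5 draws. For shTSC2 versus control it recovered 83.5% of log2 changes of 1, 98.2% of changes of 2 and 7.19% of changes of 0.5, with 3.52% false calls. For shTSC2-adapted versus control the shares were 84.2%, 98.8% and 6.97% with 4.95% false calls, and for shTSC2-adapted versus shTSC2 85.5%, 98.7% and 8.86% with 4.26%. A simulated list lowered by 0.5 was recovered in 20 of 20 simulations. The simulated genes varied independently of each other, so this does not cover lists whose genes vary together. With 200 changed genes, against 3833 called in shTSC2 versus control, the simulated shares may differ from those in the data.

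Alternatives were quantile normalization, median centring, leaving out genes below the median level, testing every probe set, eBayes with trend and robust settings, fitting only the 4 arrays compared, array weights, the replicate number as a block, and leaving out each array, where the lone array of a group is taken to vary like the other groups. After the data were seen, a crossed replicate block and the removal of a trend with gene span were added. That removal subtracts from each array a smooth curve of the log10 span fitted to the deviations from the gene means.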

Results

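Expression was measured on 6 microarrays in Du145 cells, a human prostate carcinoma line, in which the tumour suppressor gene TSC2 had been targeted by a short hairpin RNA carried by a lentivirus. TSC2 and TSC1 form a complex that restrains the growth kinase mTORC1 through the small GTPase RHEB. The cells were kept at 1% oxygen, and RNA was taken after 24 h of hypoxia. The arrays fell into 3 groups of 2: control cells, knockdown cells (shTSC2), and cells that the labels call adapted from the knockdown (shTSC2-adapted). The labels do not say what the adaptation was, whether control cells received a virus, or whether arrays of one group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. Median intensities were 58.1 to 63.1 over 33297 probe sets. Across the 18417 genes tested, which are not independent replicates, arrays of one group correlated at Pearson r = 0.997 in control, 0.990 in shTSC2 and 0.993 in shTSC2-adapted, against 0.971 to 0.973 between control and shTSC2 arrays. The first principal component held 63.9% of the variance and set the shTSC2 arrays (33.4 and 33.6) apart from the control (-22.6 and -24.4) and shTSC2-adapted arrays (-10.8 and -9.27). All values below are log2 intensities, changes are differences of group means with their standard error (SE, n = 2 per group), and adjusted p-values come from limma over 18417 genes, two-sided.

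TSC2 was lower on all 4 knockdown arrays. Its log2 intensity was 7.52 and 7.59 on the control arrays, 6.67 and 6.55 on the shTSC2 arrays, and 6.54 and 6.48 on the shTSC2-adapted arrays. In shTSC2 it fell by 0.95 (SE 0.10, adjusted p = 0.00102), which leaves 51.9% of the control level (95% interval 44.4% to 60.8%). In shTSC2-adapted it fell by 1.04 (SE 0.10, adjusted p = 0.0241), which leaves 48.5% (41.4% to 56.7%). The difference between the knockdown groups was -0.10 (95% interval -0.33 to 0.13, adjusted p = 0.564). The shTSC2-adapted call ended without control 1 (adjusted p = 0.386), control 2 (0.373), shTSC2-adapted 1 (0.169) or shTSC2-adapted 2 (0.0973), and with every probe set tested (0.244), over a range of 0.00354 to 0.386 for all settings. RHEB, the GTPase on which the TSC complex acts, fell in shTSC2 (-0.55, SE 0.12, adjusted p = 0.0168), a call that ended without control 1 (0.111) or control 2 (0.123), and stood at -0.27 in shTSC2-adapted (adjusted p = 0.414). TSC1 (0.04) and MTOR (0.12) did not pass in shTSC2 (adjusted p = 0.835 and 0.517). DDIT4, a stress- and hypoxia-induced inhibitor of mTORC1 signalling, fell in shTSC2 (-1.22, SE 0.19, adjusted p = 0.00478; 0.0522 without control 2) and was higher in shTSC2-adapted than in shTSC2 (1.78, SE 0.19, adjusted p = 0.00288).

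**Figure D1:**
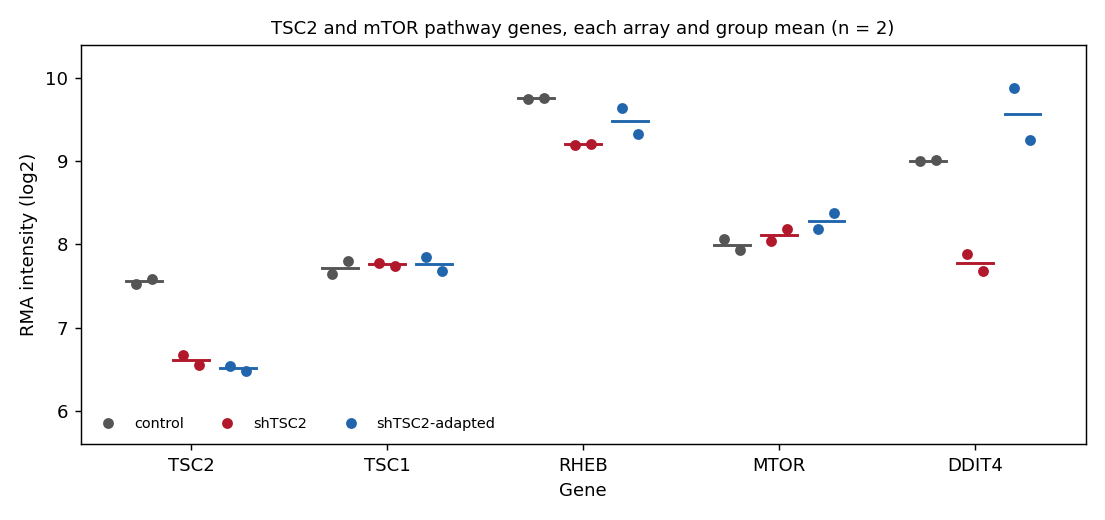
Log2 RMA intensity (vertical axis) of TSC2, TSC1, RHEB, MTOR and DDIT4 on each array (points) with group means of 2 arrays (lines), by group. TSC2 lies between 6.48 and 6.67 on the 4 knockdown arrays and at 7.52 and 7.59 on the control arrays, while DDIT4 is lowest in shTSC2 (mean 7.78) and highest in shTSC2-adapted (mean 9.56).

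The first comparison asked which transcripts differ between shTSC2 and control Du145 cells under hypoxia. Effects of the virus or the hairpin itself cannot be told apart here from those of lower TSC2. In shTSC2, all 39 genes of the mitosis list, 12 of 17 replication-dependent histones and 12 of 28 genes of sterol and fatty acid synthesis fell, while 13 of 28 NF-kB and cytokine genes and 6 of 11 antigen presentation genes rose. Among the largest falls were the histone genes H2BC14 (-3.81, SE 0.11), H3C11 (-3.64, SE 0.36), H1-5 (-2.76), H2AC4 (-2.71), H2BC4 (-2.56) and H4C2 (-2.50). They were followed by DAB2, an endocytic adaptor (-2.44), ASPM, a spindle pole protein (-2.44), KIF14, a mitotic kinesin (-2.42), and PLK1, a kinase that drives mitotic entry and progression (-2.42). Adjusted p-values of these 10 genes lay between 3.54e-05 and 0.00268. The largest rises were in SAA2 (3.10, SE 0.44) and SAA1 (2.87, SE 0.39), which encode the acute-phase protein serum amyloid A, although the other SAA2 probe set stood at 1.25 and did not pass (adjusted p = 0.0789). NFKBIZ, a nuclear regulator of NF-kB target genes, followed (2.70, SE 0.17). SLC2A3, a high-affinity glucose transporter, rose by 2.60, the chemokines CXCL2 and CXCL8 by 2.54 and 2.01, and the polyamine-catabolising enzyme SAT1 by 2.35. The stress-induced transcription factors FOS and ATF3 rose by 2.32 and 2.02, and PTGS2, the inducible prostaglandin synthase, by 1.98. The control values of PTGS2 (4.20 and 4.26) lay below the lower quartile of all probe sets (4.28), so the size of its change and its rank are uncertain. These 10 genes had adjusted p-values between 0.000256 and 0.0353.

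Mitosis showed the most complete shift of the gene lists fixed before the data were examined. All 39 genes of the mitosis and G2/M list fell, with a median of -1.20 (camera adjusted p = 2.13e-30; adjusted p = 0.136 with an estimated correlation), and all 39 also fell when adjusted over the list alone. Of 17 replication-dependent histones, 12 fell, 13 when adjusted over the list alone, none rose, and the median was -1.18 (adjusted p = 2.22e-08; adjusted p = 0.526 with an estimated correlation). Per array against the control mean, the histone median was -0.94 on shTSC2 1 and -1.615 on shTSC2 2, while that of mitosis was -1.255 and -1.215. Genes of DNA replication and G1/S did not share the fall: of 43, 12 rose and 2 fell, 13 and 5 when adjusted over the list alone, around a median of 0.13 (adjusted p = 0.0245; adjusted p = 0.671 with an estimated correlation). CCNE1, the cyclin of the G1/S transition, rose by 1.79 (SE 0.18, adjusted p = 0.00102) and UNG, a uracil-DNA glycosylase, by 1.07, whereas GINS1, part of the replicative helicase, and BRCA1, a DNA repair gene, fell (-0.61 and -0.54, adjusted p = 0.0207 and 0.0140), BRCA1 standing at -0.32 and not passing with the gene length trend removed (adjusted p = 0.107). The call of the DNA replication list ended without control 2 (adjusted p = 0.161) or shTSC2 1 (0.115).

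Of 28 genes on the list of SREBP targets, 12 fell and none rose, with 14 falling when adjusted over the list alone and a median of -0.43 (adjusted p = 8.03e-06; adjusted p = 0.577 with an estimated correlation). The sterol enzyme SQLE fell by 1.66 and the fatty acid elongase ELOVL6 by 1.61, while SCD, a fatty acid desaturase (0.30, adjusted p = 0.200), and SC5D, a late sterol enzyme (0.17, adjusted p = 0.519), did not pass. Of 31 ATF4 targets, 9 fell and 2 rose, 9 and 5 when adjusted over the list alone, with a median of -0.28 (adjusted p = 0.0155; adjusted p = 0.604 with an estimated correlation). ATF4 itself, the transcription factor of the amino acid response, fell by 1.25 (SE 0.10) on its brighter probe set but stood at -0.24 on the other, which did not pass (adjusted p = 0.399), and SLC7A11, a cystine transporter, fell by 2.30 (SE 0.27). ATF3 rose, and DDIT3 stood at 0.65 (adjusted p = 0.0524). Of 17 aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 9 fell and 3 rose, the same numbers when adjusted over the list alone, with a median of -0.41 (adjusted p = 0.0155; adjusted p = 0.582 with an estimated correlation). SARS1 fell by 1.34 and AARS1 by 0.83, while KARS1 (0.50) and VARS1 (0.56) rose. The calls of both the ATF4 and synthetase lists ended with quantile normalization (adjusted p = 0.0619 each), with dim genes left out (0.162 each) and without control 1 (0.0812 and 0.0703), and that of the ATF4 list without shTSC2 1 (0.116).

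Of 28 NF-kB and cytokine genes, 13 rose, 15 did not pass and none fell, with 18 rising when adjusted over the list alone, with a median of 0.48 (adjusted p = 1.38e-08; adjusted p = 0.526 with an estimated correlation). Besides NFKBIZ and CXCL2, which led the list, its lowest member was IL11 at -0.03 (adjusted p = 0.912). Of 11 antigen presentation genes, 6 rose and none fell, 6 also when adjusted over the list alone, with a median of 0.43 (adjusted p = 0.00147; adjusted p = 0.526 with an estimated correlation). TAP1, a subunit of the peptide transporter for class I presentation, rose by 1.97 (SE 0.12) and PSMB9, an immunoproteasome subunit, by 1.57 (SE 0.19), while HLA-DMA (-0.07) and HLA-DMB (-0.06), which act in class II presentation, did not pass (adjusted p = 0.881 and 0.922). Of 41 interferon-stimulated genes, 2 rose and 3 fell, 1 and 3 when adjusted over the list alone, and the list did not shift (median 0.01, adjusted p = 0.873). Of 24 genes of the MAPK immediate response, 7 rose and 3 fell, 7 and 5 when adjusted over the list alone (median 0.30, adjusted p = 0.0328; adjusted p = 0.651 with an estimated correlation). EREG, an EGF receptor ligand, rose by 1.94, while the pathway's negative regulators DUSP1 (-0.95) and SPRED1 (-0.57) fell. That call ended with dim genes left out (adjusted p = 0.0822), with the gene length trend removed (0.113), and without control 2 (0.0590) or shTSC2 1 (0.151).

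Of 43 nuclear-encoded genes of oxidative phosphorylation, 16 rose and 1 fell, 18 and 1 when adjusted over the list alone, with a median of 0.30 (adjusted p = 7.44e-06; adjusted p = 0.566 with an estimated correlation). COX7B, of cytochrome c oxidase, rose by 0.88 and ATP5MC1, of ATP synthase, by 0.78, while NDUFV2, of complex I, fell by 0.47. Of 36 ribosome biogenesis genes, 11 rose and 1 fell, 15 and 2 when adjusted over the list alone (median 0.14, adjusted p = 0.0155; adjusted p = 0.671 with an estimated correlation), led by NOLC1 (0.97) and PNO1 (0.97), with DKC1 at -0.58 (adjusted p = 0.0499). The ribosome biogenesis call ended without control 2 (adjusted p = 0.0590) or shTSC2 2 (0.270). Targets of the hypoxia-inducible factors did not shift as a list of 27 (median -0.13, mean -0.07, adjusted p = 0.403). Of its members, SLC2A3 and ADM rose and SLC2A1, INSIG2, VLDLR and KDM4B fell, the last 2 named after their values were seen, and the same numbers passed when adjusted over the list alone. Within this list the glucose transporters SLC2A3 (2.60) and SLC2A1 (-1.34, SE 0.10, adjusted p = 0.000504) went opposite ways, and INSIG2, which retains SREBP in the endoplasmic reticulum, fell by 1.43. Of 17 glycolysis genes, LDHA fell (-0.47, adjusted p = 0.0444) and 16 did not pass, with 0 calls when adjusted over the list alone (limma). GPI (0.32) and ENO2 (0.28) were the highest (adjusted p = 0.108 and 0.0742). The glycolysis list had a median of 0.01 and a mean of -0.02 (adjusted p = 0.915). Of 31 components of the mTOR pathway, 10 fell and 1 rose, as when adjusted over the list alone, and the list did not pass with camera (median -0.05, adjusted p = 0.114) but was lower with fry (adjusted p = 0.0291). GRB10, an adaptor phosphorylated by mTORC1, fell by 1.16 and RPS6KB2, a ribosomal S6 kinase, rose by 0.77.

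In all, 3833 genes changed in shTSC2, 1266 higher and 2567 lower, and 710 of them by 2-fold or more (118 higher and 592 lower). With each array centred on its median, the split was 868 higher and 2962 lower. Leaving out control 1 gave 1484 genes and leaving out control 2 gave 1175. Camera called 13 of 34 lists (8 up, 5 down). No list passed with an estimated correlation, where the lowest adjusted p of 0.136 belonged to mitosis. Fry, which tests each list by itself, called 12 lists (5 up, 7 down), of which 7 were also called by camera. The calls of sterol and fatty acid synthesis, ATF4 targets and oxidative phosphorylation (adjusted p = 0.0598 each), MAPK response and DNA replication (0.159 each) and ribosome biogenesis (0.175) ended with fry. With their calls kept, the medians of ribosome biogenesis and DNA replication were 0.21 and 0.20 with quantile normalization and 0.08 and 0.07 with median centring, which also gave 0.11 for the neuroendocrine and 0.10 for the lymphoid and myeloid markers, and that of antigen presentation was 0.64 with dim genes left out. The 5 lists called by fry alone were mTOR components (0.0291), NRF2 and oxidative stress (0.0325), growth factor receptors and FOXO targets (0.0445) and pentose phosphate (0.0462), all lower, and embryonic kidney markers (0.0291), higher. Of 56 named genes that passed, 22 did not pass without at least 1 of the 6 arrays (adjusted p between 0.0505 and 0.280). They were LDHA and DKC1 without any array except shTSC2 2, SNAP25 and VARS1 without shTSC2 2, ADM, CXCL8, DKC1, FCER1G, GINS1, LDHA, SNAP25, SPRED1 and VARS1 without shTSC2 1, and AARS1, ADM, BRCA1, COX7B, CXCL8, DKC1, FCER1G, FOS, KARS1, LDHA, NDUFV2, RHEB, SNAP25 and SPRED1 without either control. GINS1 was also lost without control 1, and ATP5MC1, CD68, CXCL2, DDIT4, DUSP1, RPS6KB2 and VARS1 without control 2. With the gene length trend removed, BRCA1, ADM (0.38, adjusted p = 0.0789), VARS1 (0.48, 0.0547), SPRED1 (-0.37, 0.0672) and FCER1G (0.48, 0.0717) did not pass. With every probe set tested, ADM, CXCL8, DKC1, FCER1G, GINS1, LDHA, SNAP25, SPRED1 and VARS1 did not pass (adjusted p between 0.0569 and 0.118). Nor did DKC1 (0.0868), FCER1G (0.0547) and SNAP25 (0.0843) with quantile normalization, SNAP25 (0.0906) and VARS1 (0.0545) with median centring, LDHA (0.0665) and DKC1 (0.0783) with only the 4 arrays compared, or VARS1 (0.0578) with array weights.

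Markers of other cell types also moved. Of 9 markers of the embryonic kidney lines used for packaging virus, 3 rose and 1 fell, 4 and 1 when adjusted over the list alone, and the list, with the largest median of the other cell types (0.34), passed with fry (adjusted p = 0.0291) but not with camera (0.114). Of 15 lymphoid and myeloid markers, FCER1G (0.62) and CD68 (0.62), a lysosomal protein, rose (list median 0.16, adjusted p = 0.0127; adjusted p = 0.526 with an estimated correlation). Of 12 neuroendocrine markers, SCG5 (0.88) and SNAP25 (0.46) rose, and SCG3 stood at -0.02 (list median 0.17, adjusted p = 0.0229; adjusted p = 0.526 with an estimated correlation). The last 2 lists each held 2 rises when adjusted over the list alone. Their calls ended with quantile normalization (0.0619 each) and without shTSC2 2 (0.0797 for lymphoid and myeloid, 0.172 for neuroendocrine), the neuroendocrine call also without control 2 (0.0558) and the lymphoid and myeloid call also with the gene length trend removed (0.151).

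Gene length ran through the whole comparison. Across 16903 protein-coding genes, which are not independent replicates, the change in shTSC2 fell with the span of the gene in the reference (Spearman rho -0.33), while it was -0.10 for shTSC2-adapted against control and 0.33 for shTSC2-adapted against shTSC2. Among the shortest eighth of genes, with a median span of 2.56 kb, 9.09% rose and 3.98% fell. Among the longest eighth, with a median span of 232 kb, 1.28% rose and 31.3% fell. Genes that fell had a median span of 64.8 kb and genes that rose of 15.4 kb. All 4 pairs of a shTSC2 and a control array showed the trend (rho -0.26 to -0.35), and pairs within a group reached at most 0.12 in size. With this trend removed, a setting chosen after the data were seen, 3634 genes changed, 2914 of them among the 3833, and the mitosis list kept a median of -1.22. Among lists that kept their calls, the median in shTSC2 went to 0.16 for oxidative phosphorylation, 0.27 for antigen presentation and 0.09 for ribosome biogenesis, and in shTSC2-adapted against shTSC2 to -0.19 for NF-kB and cytokines, -0.27 for antigen presentation and -0.10 for neuroendocrine markers.

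**Figure D2:**
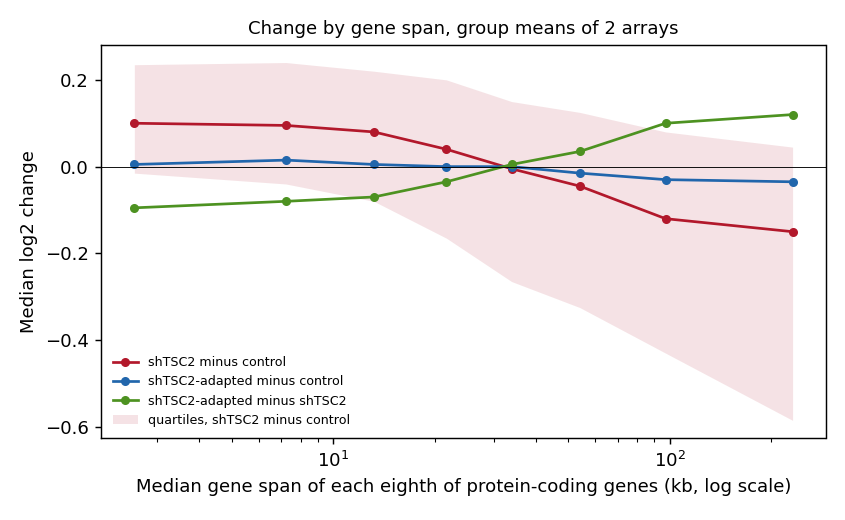
Median log2 change of protein-coding genes in 8 equal bins of gene span (horizontal axis, median span of the bin in kb, log scale) for the 3 comparisons, with the quartiles of shTSC2 minus control shaded. The shTSC2 minus control medians go from 0.10 in the shortest bin to -0.15 in the longest, and the shTSC2-adapted minus control medians from 0.005 to -0.035.

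The comparison of shTSC2-adapted with control cells asked what stayed different in the adapted cells while TSC2 was low. SLC2A3 was 3.56 log2 units above control (SE 0.24, adjusted p = 0.0190), and 4 of 39 mitosis genes and 2 of 35 matrix genes fell. The other largest rises were in MS4A15 (1.57), LONRF2 (1.19), the mucin MUC1 (1.04), KLB, a co-receptor for endocrine fibroblast growth factors (1.00), and VXN (0.94). RRAGD, a Rag GTPase of amino acid signalling to mTORC1, rose by 0.83, the circadian transcription factor NPAS2 by 0.76, UTP4, which acts in ribosomal RNA processing, by 0.75, and the sialyltransferase ST3GAL4 by 0.74. The largest falls were in DAB2 (-2.01, SE 0.21), CCDC80, an extracellular protein (-1.91), TCP11L2 (-1.47), FBLN1, which encodes the matrix protein fibulin-1 (-1.38), the mitotic kinesins KIF20A (-1.37) and CENPE (-1.28), CILK1, a ciliary kinase (-1.17), MAP3K3, a MAP kinase kinase kinase (-1.17), TLE4, a transcriptional co-repressor (-1.12), and FAT4, an atypical cadherin (-1.12). These 20 genes had adjusted p-values between 0.0190 and 0.0477.

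All 39 mitosis genes were below control in shTSC2-adapted. Of these, 4 fell, and 34 fell when adjusted over the list alone, with a median of -0.56 (camera adjusted p = 7.08e-33; adjusted p = 0.121 with an estimated correlation). The 17 histones had a median of -0.39 with 0 calls by limma and 1 fall when adjusted over the list alone (adjusted p = 1.81e-05; adjusted p = 0.595 with an estimated correlation), led by H2BC12 (-0.86, adjusted p = 0.0680) and H4C2 (-0.59, adjusted p = 0.348). The histone median was -0.175 on shTSC2-adapted 1 and -0.59 on shTSC2-adapted 2, and the call ended without the latter array. The sterol and fatty acid list, lower in shTSC2, was above control here: its median was 0.52, with 26 of 28 genes higher, 0 past the threshold by limma over all genes, and 17 rising and 1 falling when adjusted over the list alone (adjusted p = 2.40e-13; adjusted p = 0.481 with an estimated correlation). ACSS2, which makes acetyl-CoA from acetate, stood at 1.57 (SE 0.38, adjusted p = 0.146) and HMGCS1, an enzyme of the mevalonate pathway, at 0.84 (SE 0.23, adjusted p = 0.174), against -0.35 for PMVK (adjusted p = 0.297). Of 35 matrix and basement membrane genes, 2 fell and none rose, 4 when adjusted over the list alone (median -0.13, adjusted p = 0.000265; adjusted p = 0.481 with an estimated correlation). They were FBLN1 and FN1, the gene of fibronectin (-0.94), the latter named after its value was seen, while COL4A2 stood at -1.06 (adjusted p = 0.184) and TNC at 0.31 (adjusted p = 0.333).

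Other lists shifted by small amounts with 0 members past the threshold by limma over all genes. DNA replication (median 0.17, adjusted p = 1.01e-05), ribosome biogenesis (0.17, 8.32e-05), aminoacyl-tRNA synthetases (0.15, 0.00138), oxidative phosphorylation (0.13, 0.00138), epithelial markers (0.16, 0.00227), NF-kB and cytokines (0.11, 0.0106) and mitochondrial biogenesis (0.14, 0.0140) were higher. The list of growth factor receptors and FOXO targets was lower (-0.14, 0.0106). With an estimated correlation their adjusted p-values were 0.481 to 0.598. Adjusted over the list alone, 5 epithelial markers rose and 1 fell, 4 DNA replication genes rose, 2 mitochondrial biogenesis genes rose and 1 fell, and 4 growth factor and FOXO genes fell. Among the epithelial markers CDH1, the gene of E-cadherin, stood at 1.40 (SE 0.23, adjusted p = 0.0680) and MAL2 at 0.80 (adjusted p = 0.339), against -0.61 for PKP2 (adjusted p = 0.0859). CDKN1B, a cyclin-dependent kinase inhibitor on the FOXO list, stood at -0.84 (adjusted p = 0.0778). Without control 2 the FOXO (0.0830), oxidative phosphorylation (0.129) and mitochondrial biogenesis (0.184) calls ended. Without shTSC2-adapted 2 the FOXO (0.115), ribosome biogenesis (0.0689), oxidative phosphorylation (0.164) and mitochondrial biogenesis (0.164) calls ended, and without shTSC2-adapted 1 the NF-kB call (0.594, with a median of -0.005). Targets of the hypoxia-inducible factors did not shift (median -0.07, mean 0.07, adjusted p = 0.745). SLC2A3 rose and 26 of the 27 genes did not pass, EGLN3 standing at 0.48 (adjusted p = 0.187) and LOX at -0.67 (adjusted p = 0.295), with 2 rises and 1 fall when adjusted over the list alone. The glycolysis (median 0.01, adjusted p = 0.3998) and ATF4 (0.02, 0.198) lists did not shift and had 0 calls by limma on either adjustment. On the mTOR list (-0.03, 0.693) RRAGD rose and TSC2 fell, with 1 rise and 3 falls when adjusted over the list alone, and EIF4EBP2, a repressor of translation initiation, stood at -1.02 (adjusted p = 0.0636).

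In shTSC2-adapted, 48 genes differed from control, 10 higher and 38 lower, and 2317 genes had an unadjusted p under 0.05. The count was 0 without control 1, control 2, shTSC2-adapted 1 or shTSC2-adapted 2 (1301, 1081, 1706 and 2262 genes at an unadjusted p under 0.05), and 248 without either shTSC2 array. The 20 named genes other than TSC2 lost their calls in each of the first 4 cases (adjusted p between 0.0747 and 0.515), and with every probe set tested (0.244 to 0.294). Camera called 12 of 34 lists (8 up, 4 down), 0 passed with an estimated correlation, where the lowest adjusted p of 0.121 belonged to mitosis, and fry called mitosis alone, with adjusted p-values of 0.0783 to 0.543 for the other 11. With their calls kept, the medians of oxidative phosphorylation (0.08) and NF-kB and cytokines (0.07) were smaller with median centring, and those of NF-kB and cytokines (0.24) and matrix genes (-0.22) larger in size with dim genes left out.

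The third comparison set shTSC2-adapted against shTSC2, between which TSC2 did not pass. Here 32 of 39 mitosis genes, 9 of 17 histones and 21 of 28 sterol and fatty acid genes rose, and 9 of 28 NF-kB and cytokine genes fell. H3C11 (3.10, SE 0.36), H2BC14 (2.82, SE 0.11), H2BC4 (2.17), H1-5 (2.17), H2AC4 (2.15), H1-4 (2.06) and H4C2 (1.91) led the rises, together with HMGCS1 (2.09, SE 0.23), SQLE (1.99, SE 0.16) and ACSS2 (1.98, SE 0.38). The largest falls were in SAA2 (-3.01, SE 0.44; -0.95 on its other probe set, which did not pass, adjusted p = 0.200), SAA1 (-2.81), NFKBIZ (-2.76, SE 0.17), C3, the central complement component (-2.23), FOS (-2.0), the arrestin-domain protein ARRDC4 (-1.97), PTGS2 (-1.92), the chemokine receptor CXCR4 (-1.76), RGS2, a regulator of G protein signalling (-1.68), and LSMEM1 (-1.63). These 20 genes had adjusted p-values between 0.000322 and 0.0259. PTGS2 stood at 4.27 and 4.32 on shTSC2-adapted 1 and 2, near the lower quartiles of those arrays (4.35 and 4.27). The size of its change and its rank are therefore uncertain.

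Of 28 sterol and fatty acid genes 21 rose and none fell, 24 when adjusted over the list alone, with a median of 1.02 (camera adjusted p = 5.27e-17; adjusted p = 0.419 with an estimated correlation), and the lowest was PMVK at -0.01 (adjusted p = 0.982). Of 39 mitosis genes 32 rose, 35 when adjusted over the list alone, with a median of 0.77 (adjusted p = 7.86e-22; adjusted p = 0.219 with an estimated correlation). ASPM and TOP2A, a topoisomerase of mitotic chromosomes, rose by 1.73 each, and PTTG1, the gene of securin, stood at -0.12 (adjusted p = 0.550). Of 17 histones 9 rose, 11 when adjusted over the list alone, with a median of 0.63 (adjusted p = 2.28e-06; adjusted p = 0.524 with an estimated correlation), H3C10 standing lowest at -0.27 (adjusted p = 0.598). Among aminoacyl-tRNA synthetases 10 of 17 rose, 13 when adjusted over the list alone (median 0.46, adjusted p = 1.50e-05; adjusted p = 0.419 with an estimated correlation), with SARS1 at 1.41 and RARS1 at 0.97. Among ATF4 targets 9 of 31 rose, 12 and 1 fall when adjusted over the list alone (median 0.24, adjusted p = 0.000308; adjusted p = 0.504 with an estimated correlation), with DDIT4 at 1.78 and CHAC1, a glutathione-degrading enzyme, at 1.74, while ATF3 stood at -0.91 (adjusted p = 0.0724). Of 27 genes of the NRF2 and oxidative stress list, 6 rose and 2 fell, 9 and 2 when adjusted over the list alone (median 0.30, adjusted p = 0.00897; adjusted p = 0.419 with an estimated correlation). SLC7A11 (1.67) and AKR1C3 (1.22) rose, and SOD2, mitochondrial superoxide dismutase (-1.29), and the quinone reductase NQO1 (-0.53) fell. The NRF2 call ended with dim genes left out (adjusted p = 0.253).

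Of 28 NF-kB and cytokine genes 9 fell and none rose, 11 when adjusted over the list alone (median -0.31, adjusted p = 3.14e-07; adjusted p = 0.419 with an estimated correlation). Of 11 antigen presentation genes 4 fell, 6 when adjusted over the list alone (median -0.41, adjusted p = 0.000909; adjusted p = 0.432 with an estimated correlation), among them TAP1 (-1.47) and PSMB9 (-1.39). On the oxidative phosphorylation list UQCRQ (-0.68) and NDUFA1 (-0.67) were among 3 falls, the third being COX6C (-0.47), named after its value was seen, and NDUFV2 rose by 0.50. Adjusted over the list alone 9 fell and 1 rose (median -0.20, adjusted p = 0.000909; adjusted p = 0.595 with an estimated correlation). Of 24 MAPK response genes 6 fell and 2 rose, 7 and 3 when adjusted over the list alone (median -0.17, adjusted p = 0.0144; adjusted p = 0.595 with an estimated correlation), with FOSB at -1.29 and DUSP1 at 0.70. The MAPK call ended without shTSC2 1 (0.140) or shTSC2-adapted 2 (0.275) and with the gene length trend removed (0.0705). Of the neuroendocrine markers SCG5 (-0.58) and SNAP25 (-0.50) fell, also when adjusted over the list alone (median -0.18, adjusted p = 0.00897; adjusted p = 0.419 with an estimated correlation), and of the lymphoid and myeloid markers FCER1G fell (-0.68), with 0 when adjusted over the list alone by limma (median -0.14, adjusted p = 0.0139; adjusted p = 0.419 with an estimated correlation). Without shTSC2 2 both marker calls ended (0.0990 and 0.145), and the lymphoid and myeloid call also with quantile normalization (0.0552) and with the gene length trend removed (0.210). Among the targets of the hypoxia-inducible factors, which did not shift (median 0.14, adjusted p = 0.275), 5 rose and 1 fell, 7 and 3 when adjusted over the list alone, with INSIG2 at 1.07 and SLC2A3 at 0.95. The glycolysis list (median 0.03, adjusted p = 0.750) had 0 calls by limma on either adjustment. On the mTOR list (median 0.08; adjusted p = 0.160 with camera and 0.0425 with fry, higher), 4 rose and 1 fell on either adjustment, RRAGD at 0.70 and RPS6KB2 at -0.49.

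In shTSC2-adapted, 2300 genes differed from shTSC2, 1703 higher and 597 lower. The count was 1113 without control 1 or control 2, 837 without shTSC2-adapted 1 and 1181 without shTSC2-adapted 2. Camera called 12 of 34 lists (6 up, 6 down), 0 passed with an estimated correlation, where the lowest adjusted p was 0.219, and fry called 12, of which 9 were also called by camera. The calls of histones (adjusted p = 0.0963), oxidative phosphorylation (0.174) and MAPK response (0.239) ended with fry. The 3 lists called by fry alone were mTOR components, pentose phosphate and epithelial markers, all higher (0.0425 each). Of 45 named genes that passed, 19 did not pass without at least 1 array (adjusted p between 0.0502 and 0.214). They were FCER1G, NDUFV2, RPS6KB2, SLC2A3, SNAP25 and SPRED1 without shTSC2 1, shTSC2-adapted 1, shTSC2-adapted 2 or either control (RPS6KB2 and SNAP25 also without shTSC2 2), FOS, NQO1 and RARS1 without either shTSC2-adapted array or either control, and ACSS2 and DUSP1 without either control or shTSC2-adapted 1 (DUSP1 also without shTSC2 2). NDUFA1 was lost without any shTSC2 or shTSC2-adapted array, LSMEM1 without either shTSC2-adapted array, AKR1C3, H2AC4, SAA1, SLC7A11 and UQCRQ without shTSC2-adapted 1, and SCG5 without shTSC2-adapted 2. With the gene length trend removed, FCER1G (-0.54, adjusted p = 0.0702), NDUFA1 (-0.54, 0.0541), RPS6KB2 (-0.37, 0.0719) and SPRED1 (0.39, 0.0787) did not pass. With every probe set tested, ACSS2, AKR1C3, DUSP1, FCER1G, FOS, H2AC4, LSMEM1, NDUFA1, NDUFV2, NQO1, RARS1, RPS6KB2, SLC2A3, SLC7A11, SNAP25 and SPRED1 did not pass (0.0533 to 0.132). With only the 4 arrays compared, the same 11 genes as without either control did not pass (0.0503 to 0.0907). Nor did SNAP25 (0.0591) and SPRED1 (0.0606) with quantile normalization, RPS6KB2 (0.0531) and SNAP25 (0.0578) with median centring, or NDUFA1 (0.0814), RPS6KB2 (0.0644) and SNAP25 (0.0771) with array weights.

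**Figure D3:**
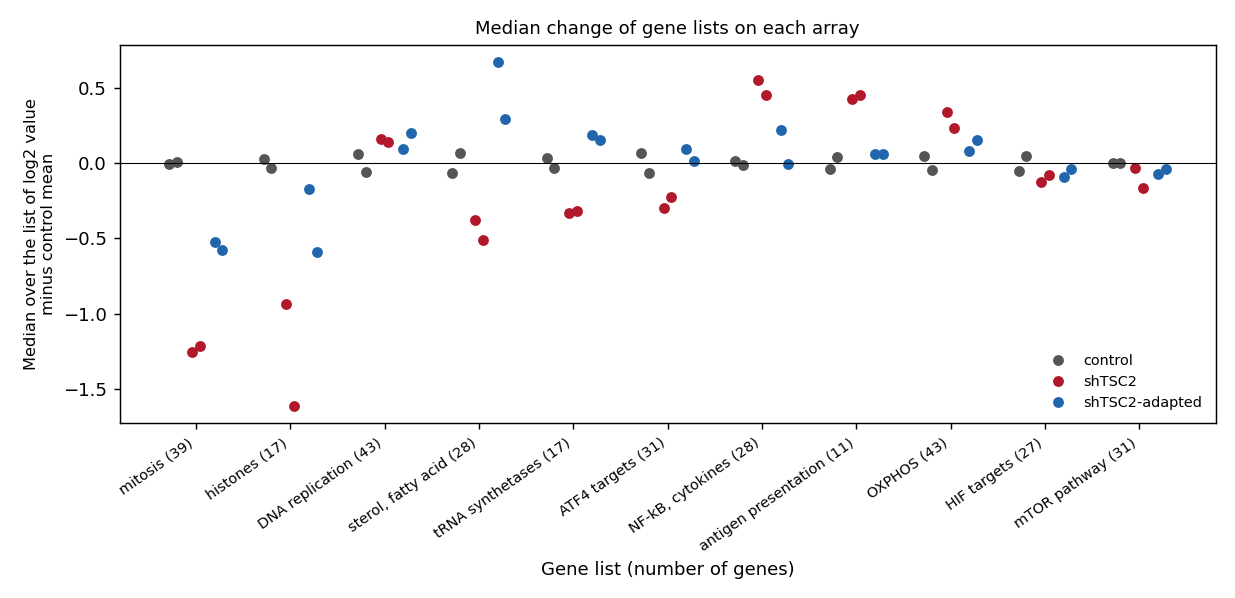
Median over each gene list of the log2 value minus the control mean (vertical axis) on each array (points, coloured by group), with the number of genes in parentheses. Mitosis lies at -1.26 and -1.22 on the shTSC2 arrays and at -0.53 and -0.57 on the shTSC2-adapted arrays, while the sterol and fatty acid list lies at -0.38 and -0.51 in shTSC2 and at 0.67 and 0.29 in shTSC2-adapted.

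The last question was how much of the shTSC2 change the adapted cells kept. Genes that fell against control in both knockdown groups numbered 36 and included TSC2, DAB2, PLK1, KIF20A, CENPE, CCDC80, FBLN1 and H2BC14, a histone outside the list of 17. Genes that rose in both numbered 4: SLC2A3, LONRF2, UTP4 and ST3GAL4. No gene changed in opposite directions by limma, among 3833 and 48 calls. Independent lists would share 5.30 falls and 0.69 rises, and 100 simulations of unchanged groups against the same controls shared 0.02 on average and at most 1. With both groups unchanged few genes pass in either comparison, so the simulated overlap is low by design. It does not measure what shared controls add beside 3833 calls. Both comparisons use the same 2 controls, so part of the excess may come from the shared controls, and the overlap was not counted with separate controls. The covariance of both sets of changes was 0.0524, against 0.0121 in the simulations, and 0.0397 to 0.0529 over the 8 combinations in which each side has its own control array. Without control 1, control 2, shTSC2-adapted 1 or shTSC2-adapted 2 the overlap was 0, without shTSC2 1 it was 212 and without shTSC2 2 it was 198. Of the 1266 genes that rose in shTSC2, 487 (38.5%) were lower again in shTSC2-adapted than in shTSC2, and of the 2567 that fell, 1429 (55.7%) were higher again, against 41.0 and 237 for independent lists. These counts share the shTSC2 arrays, whose chance values raise them. Over all 18417 genes, with no array used on both sides, shTSC2-adapted cells held 0.274 of the shTSC2 change as a net over genes (0.259 and 0.289 for the 2 combinations planned). Over all 8 combinations, which were added after the data were seen, the share was 0.256 to 0.341. These were divided by a mean covariance of the shTSC2 change, so the 0.256 is the same combination as the planned 0.259. SLC2A3 differed from both other groups in one direction, as did MS4A15, MUC1, KLB, VXN, RRAGD and NPAS2, which were higher, and FAT4, CCN2 (-0.99 against control) and DPYD (-0.73 against control), which were lower, the last 2 named after their values were seen. These calls share the shTSC2-adapted arrays, whose chance values can set a gene apart from both other groups.

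**Figure D4:**
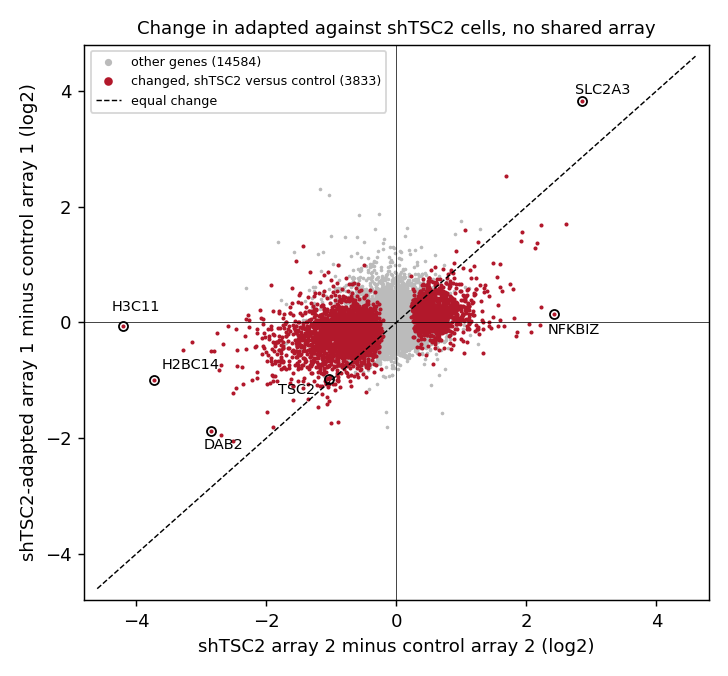
Log2 change of each gene on shTSC2-adapted array 1 against control array 1 (vertical axis) and on shTSC2 array 2 against control array 2 (horizontal axis), so that no array enters both axes. The 3833 genes changed in shTSC2 are red, and the dashed line marks equal change. SLC2A3, DAB2 and TSC2 lie on the same side of 0 on both axes, while H3C11 and NFKBIZ lie near 0 on the vertical axis.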

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

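Removing the gene length trend, the crossed replicate block and the combinations of arrays for the retained share were chosen after the data were seen, and the cause of a change was not tested except where the setting itself tests fewer or more features or arrays. Of the called named genes, 1480 results across settings kept their direction and call and 300 lost the call, and of the called lists 493 kept it and 95 lost it. No called gene changed sign, and no called list changed the direction of its test, but the median of the NF-kB list in shTSC2-adapted versus control went from 0.11 to -0.005 without shTSC2-adapted 1 (adjusted p = 0.594). With 2 arrays per group, the limits are the spread between arrays and, for dim genes, the signal over background.

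The count of genes changed in shTSC2-adapted versus control moved most: 94 with quantile normalization, 199 with median centring, 121 with dim genes left out, 248 with only the 4 arrays compared, 437 with array weights, and 0 by limma with every probe set (2812 at an unadjusted p under 0.05). The overlap with shTSC2 was 78 with quantile normalization, 174 with median centring, 110 with dim genes left out, 328 with array weights and 0 with every probe set. Over left-out arrays the count ran from 0 to 248 and the overlap from 0 to 212. For shTSC2 versus control it ran from 1175 to 3895. For shTSC2-adapted versus shTSC2 it ran from 837 to 2600, with 1170 for every probe set and 1113 for only the 4 arrays compared. The number of lists called with an estimated correlation was 0 in each comparison by camera, and 1 with fry for shTSC2-adapted versus control. TSC2 in shTSC2-adapted stayed at -1.045 with every probe set and ran from -1.08 to -1.01 over left-out arrays. The retained share was 0.237 with every probe set and 0.306 as the mean over every combination of arrays, a setting added after the data were seen that takes in controls of either number.

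The labels do not say whether array numbers mark a shared day or batch. The deviations of same-numbered arrays correlated at -0.10 for control and shTSC2, -0.19 for control and shTSC2-adapted and 0.21 for both knockdown groups. They did not go together in every pair of groups, and a batch behind some of them was not tested. With the replicate block, shTSC2-adapted versus control gave 1 gene, the overlap was 1, and TSC2 stood at -1.045 (adjusted p = 0.0515, with 0.00354 to 0.386 over all settings). In shTSC2-adapted versus control, the replicate block ended the calls of all named genes except SLC2A3 (limma adjusted p between 0.0515 and 0.0903). In shTSC2 versus control it ended those of VARS1 (0.0510), DKC1 (0.0602) and SNAP25 (0.0555). In shTSC2-adapted versus shTSC2 it ended those of RPS6KB2 (0.0517), SPRED1 (0.05002), SNAP25 (0.0583) and FCER1G (0.0540). With the crossed block the counts were 4212, 148 and 2732.

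Signs changed for 22 results that had not passed, at most 0.42 in size. The glycolysis list stood at 0.01 with fry (shTSC2 versus control) and 0.03 with dim genes left out (shTSC2-adapted versus shTSC2), where median and test differ in sign, as they did for the hypoxia list in shTSC2-adapted versus control (-0.07 with fry, -0.065 with quantile normalization). TSC1 moved to -0.02 with median centring (shTSC2 versus control) and, in shTSC2-adapted versus shTSC2, to -0.055 with quantile normalization and -0.069 with the length trend removed. That removal also gave -0.022 for MTOR, -0.061 for NLRC5 and 0.054 for PMVK in that comparison and 0.0095 for SCG3 in shTSC2 versus control, and median centring gave 0.01 for PMVK.

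Over left-out arrays, shTSC2 versus control ran from -0.98 to 0.14 for ALDOC, -0.385 to 0.255 for HLA-DMA, -0.535 to 0.425 for HLA-DMB, -0.175 to 0.125 for IL11, -0.16 to 0.12 for SCG3, -0.04 to 0.12 for TSC1 and -0.055 to 0.035 for the glycolysis list. For shTSC2-adapted versus control it was -0.245 to 0.155 for HK1, -0.215 to 0.025 for MMP1, -0.04 to 0.13 for TSC1, -0.025 to 0.07 for glycolysis and -0.15 to -0.02 for the hypoxia list. For shTSC2-adapted versus shTSC2 it was -0.065 to 0.075 for CD79B, -0.645 to 0.115 for H3C10, -0.125 to 0.835 for HLA-DMB, -0.055 to 0.225 for IL24, -0.47 to 0.04 for PFKM, -0.06 to 0.05 for PMVK, -0.08 to 0.09 for TSC1 and -0.045 to 0.065 for glycolysis.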

Other observations

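The tests below of unsilenced cells, non-polyadenylated RNA, cycling cells, cells held before S phase, signal intensity, single arrays and RNA integrity were chosen after related results had been seen, and the gene length setting after the data were seen. Several gene groups did not shift as lists in shTSC2 with camera, whose adjusted p-values follow, although single members changed. Of 24 genes of mitochondrial biogenesis and the tricarboxylic acid cycle, 10 rose and 6 fell around a median of 0.20 (adjusted p = 0.341), and of 19 cell cycle inhibitors and p53 targets, 6 rose and 4 fell (median 0.16, adjusted p = 0.232). Among 28 autophagy genes 4 rose and 8 fell (-0.04, 0.442), among 36 lysosome genes 3 rose and 4 fell (0.05, 0.379), and among 27 NRF2 and oxidative stress genes 2 rose and 8 fell (-0.16, 0.141; 0.0325 with fry). Of 24 unfolded protein response genes 5 rose and 2 fell (0.13, 0.108), of 13 heat shock genes 2 fell (0.03, 0.915), of 22 apoptosis regulators 5 rose and 3 fell (0.13, 0.403), and of 6 pentose phosphate genes 1 rose and 2 fell (-0.35, 0.232; 0.0462 with fry). Cytosolic ribosomal protein genes moved little: of 43, 1 rose and 6 fell (-0.04, 0.915). Of 21 growth factor receptors and FOXO targets 2 rose and 7 fell (-0.12, 0.141, and 0.0445 with fry), of 35 matrix genes 6 fell (-0.05, 0.186), of 29 epithelial markers 2 rose and 4 fell (0.07, 0.915), and of 36 mesenchymal markers 2 rose and 4 fell (0.02, 0.915). The 10 luminal prostate markers (0.09, 0.442) and the 10 endothelial markers (0.03, 0.713) held 0 calls by limma, also with each list adjusted alone.

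Small non-coding RNA genes, grouped after the data were seen, did not follow the histones. In shTSC2, 61 H/ACA box small nucleolar RNA genes had a median change of 0.24 (8 rose, none fell), 16 small Cajal body RNA genes 0.32 (6 rose, none fell) and 115 C/D box genes 0.07 (6 rose, 3 fell). Of 66 genes with histone symbols, 32 fell and 2 rose in shTSC2 (median -0.53), and 25 rose and 2 fell in shTSC2-adapted against shTSC2 (median 0.26). In shTSC2-adapted against control their median was -0.26, and 1 fell.

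As a net over genes, most of the shTSC2 change was absent from the adapted cells, which held 0.274 of it. Single genes differed: 188 of 1266 rises and 409 of 2567 falls in shTSC2 lay on the far side of control in shTSC2-adapted, without a test. If unsilenced cells had outgrown the others, TSC2 would stand at about -0.26 against control, but its upper 95% bound in shTSC2-adapted was -0.82. Quantile normalization left the share at 0.270 (median centring cannot alter it by construction), and removing the gene length trend gave 0.287. The TSC2 bound argues against unsilenced cells. Across bins of gene span the shTSC2 medians ran only from 0.10 to -0.15, so removing the trend could move the share little. The 0.287 therefore shows only that the share does not rest on that trend. Array scaling is not decided, because RMA had already scaled the arrays and a second normalization reaches only the differences that remained. Those were not void, since quantile normalization took the count for shTSC2-adapted versus control from 48 to 94 genes. What the adaptation was, and selection of cells or a change of medium, stay open and were not tested.

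Mitosis genes and histones were lower in shTSC2 and DNA replication genes were not. With the gene length trend removed, the mitosis median was -1.22. Across bins of gene span the shTSC2 medians ran only from 0.10 to -0.15, so the removal could move the mitosis median little. The trend is thus too small to account for the mitosis fall. For the histones and the DNA replication genes no values with the trend removed are given here. A lower yield of RNA without poly(A) tails would lower small nucleolar and Cajal body RNA too, if it acted on them as on histone RNA, which was not tested. Their first quartile was -0.0413, above the bound of -0.59 set by the histones. Fewer cycling cells of every phase would lower DNA replication genes, whose first quartile was -0.12 against a bound of -0.60. That these genes were not lower is part of the pattern itself, so this value restates the pattern and is no separate test. Whether more shTSC2 cells were held before S phase stays open: CCNE1 changed by 1.79 but was picked from this comparison, so it tests nothing, and the DNA content of the cells was not analysed here. Among genes looked up after their values were seen, CDKN1B, an inhibitor of the G1/S kinases, fell (-0.97, adjusted p = 0.00429), and MCM2 (0.04) and PCNA (0.06) did not pass (adjusted p = 0.889 and 0.728).

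Long genes were lower in shTSC2 (rho -0.33 across genes). A difference between single arrays unrelated to group is argued against, since the weakest of the 4 array pairs was -0.26 and pairs within a group stayed within 0.12 in size. These pairs reuse the same arrays. If arrays of one group came from one culture, they do not cover a difference between cultures or RNA preparations. Signal intensity stays open: the trend was -0.41 and -0.39 in the middle and highest of 3 equal groups of genes by level but -0.146 in the lowest, just short of the bound of -0.15, which was set after the trend had been seen in bright genes but before these groups were computed. Lower RNA integrity in the shTSC2 arrays cannot be told apart from an effect of the knockdown on long genes, because the value of -0.33 fits either and the length of the mature transcripts and the signal along them were not analysed here. A change in transcription elongation or in RNA stability may also give such a trend and was not tested.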
